A study of Homo sapiens with 11 samples.

How the data were processed

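RNA from sorted DC of human small intestine was measured on 11 single-colour arrays. Per the labels' protocols, total RNA was isolated with the RNeasy Plus Micro kit, amplified with the Ambion WT Expression Kit, and fragmented and labelled with biotin by the Affymetrix WT terminal labelling kit. The deposited values are log2 signals per probe set, for which the submitters' processing notes name RMA and Partek. RMA usually comprises background correction, quantile normalization and a summary of the probes of each set. Versions and settings are not given in the sources used here. No counts underlie these values, so precision was limited by the number of arrays.

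The labels gave the group and a replicate number for every array: 3 CD103+ Sirpa-, 5 CD103+ Sirpa+ and 3 CD103- Sirpa+. No pair of arrays held identical values, and correlations between arrays ran from 0.855 to 0.980. The array annotation paired 19460 of 33297 probe sets with 1 gene symbol, 1754 with several and 12083 with none. Of the first kind 19429 matched the reference table by gene ID and 31 did not, and no symbol was updated. Probe sets of several genes or of none were left out, as were 24 probe sets of XIST or Y-linked genes. Where a gene had several probe sets (768 genes), the one with the highest mean over all arrays was used, which left 18394 genes. Among the probe sets left out, 30, 14 and 35 of those with several symbols and 51, 108 and 62 of those with none passed the test in the 3 comparisons, in the order of the report.

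The design fixed before the data were examined used the deposited values with no further normalization. CD103+ Sirpa+ replicate 5 proved to be on another scale: its median was 1.47 above the median of the other arrays' medians, and its quartiles 1.45 and 1.64 above. All arrays were therefore quantile normalized over all probe sets before the fit, which is a departure from the fixed design. The values as deposited and a subtraction of array medians are given as alternatives. Quantile normalization forces 1 distribution on all arrays, so that a true shift of most genes in 1 subset would be removed.

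Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit with a mean per group and eBayes with its default prior). All 11 arrays entered 1 fit with 8 residual degrees of freedom, because a shared estimate of the spread is steadier than one from a pair of groups. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes of a comparison, and a gene was called at an adjusted p under 0.05, with no limit on fold. Genes higher in 1 subset than in both others had to be called and higher in both contrasts. All 3 pairs of groups were compared.

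Lists of genes for cell types, receptors, antigen presentation and pathways, 36 in number, were fixed together with the design and tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists of a comparison. A list needed 5 measured members. Camera compares a list with all other genes. It was repeated with an estimated correlation, and limma's fry was run beside it, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes. With an estimated correlation 2, 0 and 2 lists were called in the 3 comparisons, in order, and fry called 5, 2 and 13. List members with no probe set of their own symbol alone were not tested.

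Named genes were chosen by a rule: ITGAE and SIRPA; the 10 largest rises and 10 largest falls among called genes whose arrays did not overlap between the groups; and of each list up to 4 called members with the smallest adjusted p, or where none was called up to 2 with the largest absolute difference, as values only. Genes marking a subset were the 10 with the largest smaller difference. XIST, Y-linked genes, pseudogenes and probe sets of several genes or none were excluded. Means carry the SD over arrays, and log2 differences carry limma's standard error.

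The procedure was tested on simulated data with 200 changed genes among 18394 and seed 1. A log2 change of 2 was recovered for 100% of genes in the first comparison, 100% in the second and 97% in the last. A change of 1 was recovered for 56.7%, 67.2% and 44.8%, and a change of 0.5 for 7.46%, 1.49% and 2.99%. There were 4, 4 and 6 false calls among 113, 116 and 102. The simulated noise was independent between genes and between arrays, with the same spread of a gene in all groups. The real arrays need not meet this, so these rates may not hold for them.

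Alternatives were the deposited values, subtracted array medians, omission of genes below the median signal, the mean of a gene's probe sets, a trended and robust prior, a fit of only the groups compared, array weights, the replicate number as a block, CD103+ Sirpa+ arrays 1 to 3 only, a minimum log2 difference of 1, and omission of each array in turn. After the data were seen, 3 were added: the mean of the mast cell markers as a covariate, the interquartile range of the deposited values of each array as a covariate, and omission of CD103+ Sirpa+ replicate 5 together with CD103- Sirpa+ replicate 2. Other splits of the samples were fitted in the same way, all of them where there were at most 100. Otherwise 100 were used, the real one among them and the rest drawn.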

Results

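Human dendritic cells (DC) of the small intestine were sorted on CD103, the integrin alpha E chain encoded by ITGAE, and on Sirpa, the inhibitory receptor encoded by SIRPA, and their RNA was measured on whole-transcript arrays. The series held 11 arrays in 3 groups: 3 of CD103+ Sirpa- DC, 5 of CD103+ Sirpa+ DC and 3 of CD103- Sirpa+ DC. The deposited log2 signals of 10 arrays had medians between 5.30 and 5.51, whereas that of CD103+ Sirpa+ replicate 5 was 6.85. All values were therefore quantile normalized before the groups were compared, and the total counts of genes and lists obtained with the values as deposited are given beside the totals. The number of arrays limited the precision. The labels did not state that replicates came from separate donors, so p-values measured only the spread between these samples, which may be technical.

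**Figure D1:**
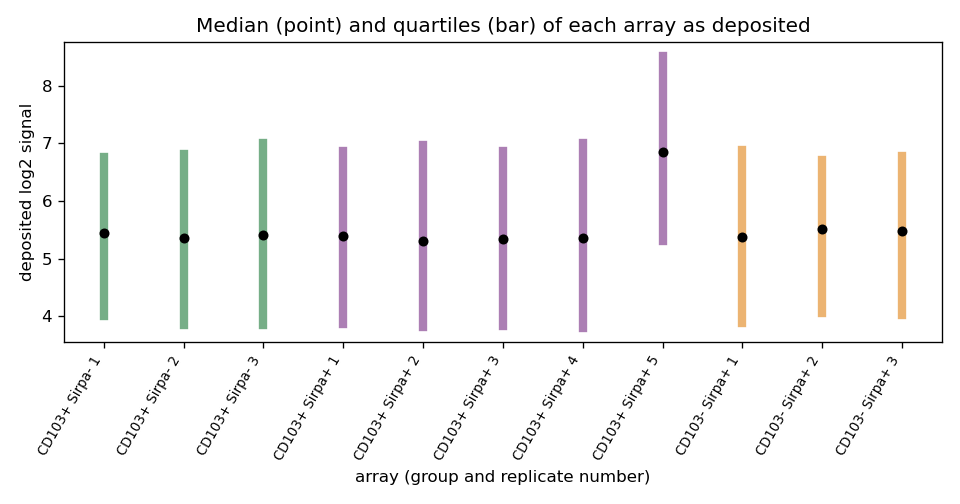
Median and quartiles of the deposited log2 signal of each array over all probe sets, with the arrays on the x axis and log2 signal on the y axis. The median of CD103+ Sirpa+ replicate 5 lay at 6.85 and those of the other 10 arrays between 5.30 and 5.51.

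The genes of the sorting gate were examined first, as a check of the labels. ITGAE had a mean log2 signal of 9.27 ± 0.25 (SD, n = 3) in CD103+ Sirpa- DC and 9.24 ± 0.43 (SD, n = 5) in CD103+ Sirpa+ DC, and was 7.56-fold lower in CD103- Sirpa+ than in CD103+ Sirpa+ DC (limma adjusted p = 2.14e-04). SIRPA was 5.25-fold lower in CD103+ Sirpa- than in CD103+ Sirpa+ DC (adjusted p = 3.99e-05), while the Sirpa+ groups differed in it by -0.20 ± 0.22 (SE) on the log2 scale (adjusted p = 0.570).

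**Figure D2:**
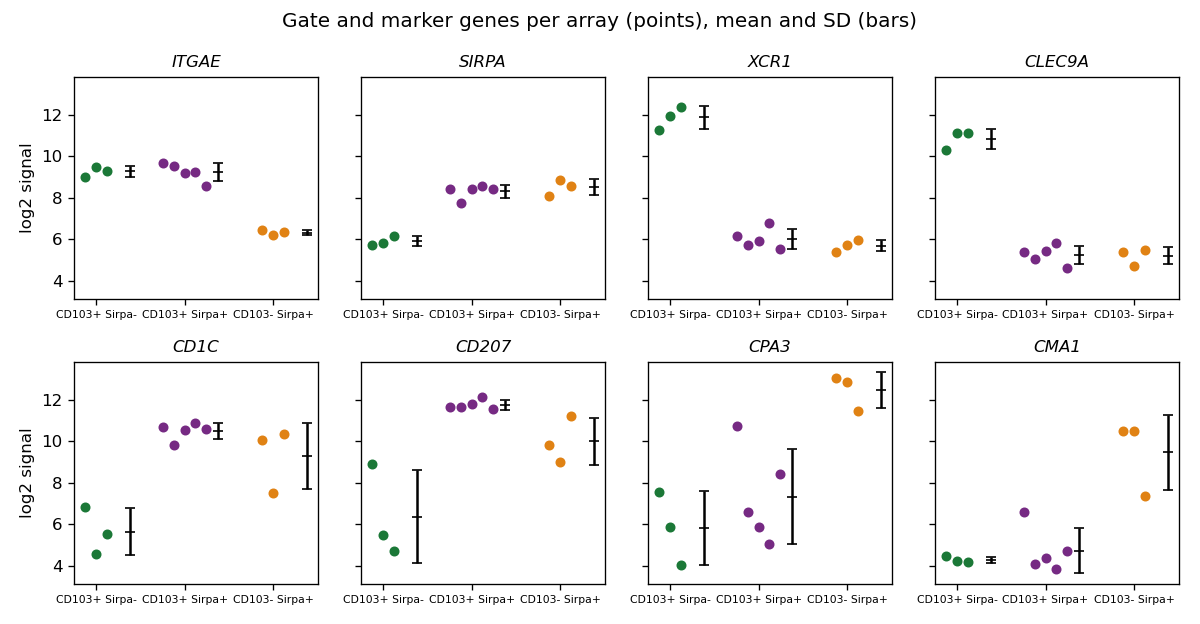
Normalized log2 signal (y axis) of 8 genes in the 3 sorted groups (x axis), with 1 point per array and the group mean with its SD. ITGAE was lower in CD103- Sirpa+ DC, SIRPA, CD1C and CD207 were lower in CD103+ Sirpa- DC, XCR1 and CLEC9A were higher in CD103+ Sirpa- DC, and CPA3 and CMA1 were higher in CD103- Sirpa+ DC.

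Among the CD103+ cells, the Sirpa- and Sirpa+ subsets were compared to find which genes separate them. XCR1, the receptor for the chemokine XCL1, was 57.8-fold higher in CD103+ Sirpa- DC, with a log2 difference of 5.85 ± 0.29 (SE, n = 3 and 5, adjusted p = 4.56e-07). CLEC9A, a C-type lectin that binds dead cells, was 47.8-fold higher, and the nucleotide pyrophosphatase gene ENPP1 was 23.0-fold higher. In CD103+ Sirpa+ DC, CD207, which encodes the lectin langerin, was 42.1-fold higher, with a log2 difference of -5.40 ± 0.74 (SE, adjusted p = 7.75e-04). CD1C and CD1E, genes of the CD1 family, were 29.0-fold and 25.4-fold higher there, and FCER1A, a chain of the IgE receptor, was 27.5-fold higher. Other genes with large differences in favour of CD103+ Sirpa- DC were TSPAN6, GPR31, PTK2, GCSAM, FMNL2, OMD and FAR2, from 25.9-fold down to 10.9-fold. The means of TSPAN6 and OMD in CD103+ Sirpa+ DC (3.74 and 2.94) lay below the lower quartile of all probe sets (4.02), where signal over background was not tested, so the size of these folds is uncertain. On the Sirpa+ side SLCO4C1, GAPT, PSTPIP2, FCGR2B, CYBB and CEACAM1 ranged from 25.8-fold to 15.2-fold. The largest differences were chosen among called genes whose arrays did not overlap between the groups, which held for 701 of all 718 called genes. Each of these genes kept its call with the values as deposited, with array medians subtracted and without any single array. With the replicate number as a block 359 of the 718 stayed called, and with CD103+ Sirpa+ arrays 1 to 3 only 339 did. Those 2 settings are not given gene by gene here.

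Marker genes of the conventional DC subset type 1 (cDC1) rose as a group in CD103+ Sirpa- DC: 19 of 22 measured genes were higher, none were lower and 3 did not pass the test (median log2 difference 2.06, camera adjusted p = 1.32e-31 and adjusted p = 0.0158 with an estimated correlation). Adjusted over the list alone, 22 were higher. They included CPNE3 (4.75-fold). Marker genes of the type 2 subset (cDC2) fell: 12 of 20 were lower, 8 did not pass, and 15 were lower when adjusted over the list alone (median -2.36, adjusted p = 2.25e-17 and adjusted p = 0.0517 with an estimated correlation). CLEC10A, a galactose-binding lectin, was 12.1-fold lower and CD1A was 9.71-fold lower.

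Fc and complement receptors also fell, with 8 of 16 lower and 8 not past the threshold (9 lower and 1 higher adjusted over the list alone; median -1.38, adjusted p = 5.26e-11 and adjusted p = 0.0167 with an estimated correlation). FCGR2B was 17.5-fold lower, the complement receptor VSIG4 11.9-fold lower and FCGR2A 6.56-fold lower. Of 25 genes of the type I interferon response, 11 were lower and 14 did not pass (15 lower adjusted over the list alone, adjusted p = 3.45e-12 and adjusted p = 0.108 with an estimated correlation). SAMD9L, a restriction factor, was 8.20-fold lower and the oligoadenylate synthetase gene OAS3 4.26-fold lower. Tissue macrophage markers were lower for 9 of 24 genes and not past the threshold for 15 (10 lower and 1 higher adjusted over the list alone, adjusted p = 7.71e-08 and adjusted p = 0.311 with an estimated correlation). Examples were CSF1R, the receptor for colony-stimulating factor 1 (12.8-fold), and MRC1, the mannose receptor (7.52-fold). Growth factor receptors of myeloid cells were lower for 4 of 22 genes and 18 did not pass (6 lower adjusted over the list alone, adjusted p = 1.26e-05 and adjusted p = 0.343 with an estimated correlation). Monocyte markers were lower for 3 of 19 genes, including the fractalkine receptor gene CX3CR1 (11.7-fold), and 16 did not pass (6 lower and 1 higher adjusted over the list alone, adjusted p = 0.0143 and adjusted p = 0.401 with an estimated correlation). The monocyte list was not called when genes below the median signal were left out (adjusted p = 0.109).

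Receptors of innate sensing went both ways. Among 19 Toll-like and NOD-like receptor genes 3 were higher, 4 were lower and 12 did not pass (3 and 5 adjusted over the list alone, adjusted p = 0.0196 and adjusted p = 0.486 with an estimated correlation). TLR7, a sensor of single-stranded RNA, was 10.3-fold lower and TLR4, the receptor for lipopolysaccharide, 7.07-fold lower in CD103+ Sirpa- DC, whereas AIM2, a sensor of cytosolic DNA, was 9.82-fold higher. Of 20 C-type lectin receptors 2 were higher, CLEC9A and CLEC1A (7.86-fold), 4 were lower and 14 did not pass (2 and 8 adjusted over the list alone, adjusted p = 0.0256 and adjusted p = 0.344 with an estimated correlation), and this list was not called when array medians were subtracted. Of 24 cytokine genes 4 were lower and 20 did not pass (5 lower adjusted over the list alone, adjusted p = 0.0256 and adjusted p = 0.183 with an estimated correlation). Those with the smallest p were IL22RA2, a soluble antagonist of interleukin 22 (10.5-fold), and IL18 (5.88-fold). Without CD103+ Sirpa- replicate 2 these 3 lists were not called (adjusted p = 0.1005, 0.0557 and 0.107). Nor were the lectin receptors without CD103+ Sirpa- replicate 3 (adjusted p = 0.0637), or the lectin receptors and cytokines without CD103+ Sirpa+ replicate 5 (adjusted p = 0.0632 and 0.0789). The Toll-like and NOD-like and the lectin receptors were not called when genes below the median signal were left out (adjusted p = 0.0938 and 0.259).

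Smaller shifts of called lists are given as counts. Cell cycle genes were higher as a list, with 2 of 25 called and 23 not past the threshold (2 adjusted over the list alone; median 0.42, adjusted p = 1.32e-04 and adjusted p = 0.486 with an estimated correlation). The list mean of CD103+ Sirpa- replicate 1 was 6.10, below all 5 CD103+ Sirpa+ arrays (6.13 to 6.58), and those of replicates 2 and 3 were 7.25 and 6.99. The mean log2 difference of this list was 0.46, against 0.81 without replicate 1 and 0.22 without replicate 2 (adjusted p = 4.28e-13 and 0.0390). Lysosomal genes were lower for 3 of 22, including LAMP1 (8.11-fold) and NPC1 (3.84-fold), with 19 not past (5 lower and 1 higher adjusted over the list alone, adjusted p = 0.0294 and adjusted p = 0.414 with an estimated correlation). DC maturation and migration genes were lower for 3 of 24 with 21 not past (4 lower and 1 higher adjusted over the list alone, adjusted p = 0.0245 and adjusted p = 0.554 with an estimated correlation). Glycolysis genes were lower for 1 of 19, HK2 (3.27-fold), with 18 not past (3 lower adjusted over the list alone, adjusted p = 0.0294 and adjusted p = 0.401 with an estimated correlation). Lipid handling genes were higher for 1 and lower for 1 of 23, with 21 not past (1 and 2 adjusted over the list alone, adjusted p = 0.0293 and adjusted p = 0.401 with an estimated correlation). Without CD103+ Sirpa- replicate 2 the maturation, glycolysis and lipid handling lists were not called (adjusted p = 0.231, 0.0774 and 0.110). The maturation list was also not called without CD103+ Sirpa- replicate 3 (adjusted p = 0.205), and its mean difference of -0.53 was -0.34 then and -0.85 without replicate 1. Glycolysis genes were not called without CD103+ Sirpa- replicate 1 (adjusted p = 0.0762). Without CD103+ Sirpa+ replicate 1 the maturation, glycolysis, lipid handling and lysosomal lists were not called (adjusted p = 0.154, 0.108, 0.108 and 0.0889), and the lysosomal list was not without CD103+ Sirpa+ replicate 4 (adjusted p = 0.0841). Leaving out genes below the median signal ended the calls of the maturation, glycolysis and lipid handling lists (each adjusted p = 0.198). Mast cell and basophil markers were lower for 1 of 11, the prostaglandin D synthase gene HPGDS (9.15-fold, from a mean of 4.00 near the lower quartile of all probe sets), with 10 not past (4 lower adjusted over the list alone; median -1.34, adjusted p = 0.00282 and adjusted p = 0.486 with an estimated correlation).

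In total 718 of 18394 genes differed between these groups, 256 higher (35.7%) and 462 lower in CD103+ Sirpa- DC, and 16 of the 36 lists passed (22 with the values as deposited). The list means of the arrays overlapped between the groups for 5 of the 16, the mast cell, Toll-like and NOD-like receptor, maturation, cell cycle and glycolysis lists. With the mast cell marker mean as a covariate the maturation, cell cycle, glycolysis, lipid handling and lysosomal lists were not called (adjusted p from 0.0689 to 0.554). With the interquartile range of each array as a covariate the Toll-like and NOD-like receptor, glycolysis, lipid handling and lysosomal lists were not (adjusted p from 0.165 to 0.319). With the values as deposited 614 genes were called, 443 of them among the 718, and 14.5% of them were higher in CD103+ Sirpa- DC; the median difference over all genes was then -0.23. Without CD103+ Sirpa- replicate 2, 416 genes and 10 lists were called, and 6 of 56 splits of these arrays gave as many lists as the real one. Splits other than the real one called a median of 8 lists.

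The CD103+ and CD103- subsets of the Sirpa+ cells were compared to find which genes go with CD103. DSG2, which encodes the desmosomal cadherin desmoglein 2, was 20.03-fold higher in CD103+ Sirpa+ DC, with a log2 difference of 4.32 ± 0.61 (SE, n = 5 and 3, adjusted p = 0.00420). CDH17, a cadherin of intestinal epithelium, was 6.73-fold higher, IL22RA2 7.03-fold and the fatty acid elongase gene ELOVL6 6.26-fold. In CD103- Sirpa+ DC the mast cell protease genes CPA3 and CMA1 were 34.8-fold and 26.6-fold higher, with log2 differences of -5.12 ± 1.09 and -4.73 ± 0.70 (SE, adjusted p = 0.0236 and 0.00531). IL1RL1, the receptor for interleukin 33, was 23.2-fold higher and CTSG, cathepsin G, 19.6-fold higher in CD103- Sirpa+ DC. ITGB1BP2, ENPP1, AKAP6, DNAJC5B and SLCO4C1 were from 6.19-fold to 5.47-fold higher in CD103+ Sirpa+ DC, with ENPP1 in CD103- Sirpa+ DC (3.72) below the lower quartile of all probe sets (4.02). RAB27B, MAOB, TPSD1, IL5RA, S100A8 and TIMP3 were from 17.1-fold to 9.82-fold higher in CD103- Sirpa+ DC.

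Mast cell and basophil markers were lower in CD103+ Sirpa+ than in CD103- Sirpa+ DC for 9 of 11 genes, and 2 did not pass (11 lower adjusted over the list alone; median -3.01, camera adjusted p = 1.41e-09 and adjusted p = 0.625 with an estimated correlation). The mean of the list was 9.65 ± 1.47 (SD, n = 3) in CD103- Sirpa+ DC, 6.54 ± 0.76 (SD, n = 5) in CD103+ Sirpa+ DC and 5.37 ± 0.57 (SD, n = 3) in CD103+ Sirpa- DC. GATA2, a transcription factor of mast cells and progenitors, was 9.56-fold lower and RGS13 7.26-fold lower in CD103+ Sirpa+ DC.

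**Figure D3:**
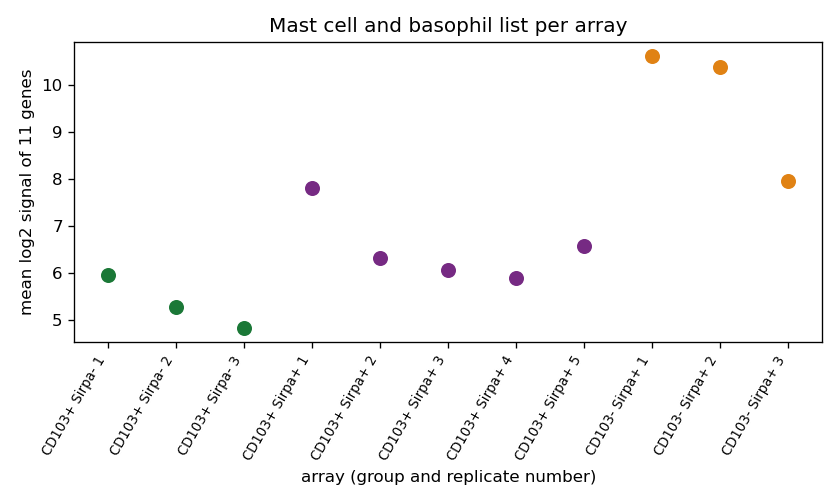
Mean normalized log2 signal of the 11 measured mast cell and basophil markers (y axis) in each array (x axis), with 1 point per array coloured by sorted group. The 3 CD103- Sirpa+ arrays lay at 10.6, 10.4 and 7.96, and the highest other array, CD103+ Sirpa+ replicate 1, at 7.82.

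Markers of B and plasma cells were lower in CD103+ Sirpa+ DC for 4 of 17 genes, with 13 not past the threshold (9 adjusted over the list alone, adjusted p = 2.05e-06 and adjusted p = 0.625 with an estimated correlation). Examples were MS4A1, which encodes CD20 (3.72-fold, adjusted p = 0.0543 without CD103+ Sirpa+ replicate 5), and BANK1 (2.21-fold). Neutrophil and eosinophil markers were lower for 4 of 12, with 8 not past (6 lower and 2 higher adjusted over the list alone, adjusted p = 0.0348 and adjusted p = 0.625 with an estimated correlation). An example was the eosinophil granule gene PRG2 (2.84-fold). The list was not called without CD103- Sirpa+ replicate 2, whose list mean was 7.06 against 6.01 and 6.20 in the other CD103- Sirpa+ arrays, or without CD103+ Sirpa+ replicate 5 (adjusted p = 0.0696 and 0.0600). BANK1 and PRG2 were not called with the values as deposited. Of the cDC1 markers 5 of 22 were higher in CD103+ Sirpa+ DC and 17 did not pass (11 adjusted over the list alone, adjusted p = 3.04e-05 and adjusted p = 0.625 with an estimated correlation). Examples were BTLA (4.10-fold) and DNASE1L3 (2.78-fold). Type I interferon response genes were higher for 8 of 25, with 17 not past (8 adjusted over the list alone, adjusted p = 7.97e-04 and adjusted p = 0.625 with an estimated correlation). Examples were IFI44L (3.19-fold) and MX1 (2.47-fold). The interferon list was not called when genes below the median signal were left out (adjusted p = 0.0620). MHC class II presentation genes were higher for 2 of 18, HLA-DOA (2.40-fold) and HLA-DMA (1.82-fold), with 16 not past (9 adjusted over the list alone, adjusted p = 2.29e-04 and adjusted p = 0.625 with an estimated correlation), and HLA-DMA was not called with the values as deposited. The MHC class II mean of CD103- Sirpa+ replicate 2 was 8.46, and those of replicates 1 and 3 (9.67 and 9.71) lay within the range of the CD103+ Sirpa+ arrays (9.35 to 10.19). Without replicate 2 the mean difference of this list went from 0.52 to 0.11 (adjusted p = 0.0316). Toll-like and NOD-like receptors were higher for 3 of 19, including LY96 (3.35-fold), with 16 not past (4 adjusted over the list alone, adjusted p = 0.00246 and adjusted p = 0.625 with an estimated correlation). CD103- Sirpa+ replicate 2 had a list mean of 5.57 against 6.39 and 6.70 in the other CD103- Sirpa+ arrays, and without it this list was not called (mean difference 0.35 against 0.67, adjusted p = 0.107). Cell cycle genes were higher for 2 of 25, including the proliferation marker MKI67 (3.30-fold), with 23 not past (7 adjusted over the list alone, adjusted p = 2.17e-05 and adjusted p = 0.625 with an estimated correlation).

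The remaining called lists moved with few or no called members. Immediate early genes were lower for 1 of 24, FOSB (2.07-fold), with 23 not past (1 adjusted over the list alone, adjusted p = 0.0248 and adjusted p = 0.625 with an estimated correlation). Neither FOSB nor this list was called with the values as deposited or with array medians subtracted. Chemokines had no called member among 24 (2 higher and 4 lower adjusted over the list alone, adjusted p = 0.0427 and adjusted p = 0.625 with an estimated correlation). Neither list was called without CD103+ Sirpa+ replicate 2 or 3 or CD103- Sirpa+ replicate 1, with adjusted p of 0.0845, 0.136 and 0.198 for the immediate early genes and 0.0564, 0.0669 and 0.0919 for the chemokines. The chemokines were not called without CD103- Sirpa+ replicate 3 either (adjusted p = 0.0801). Ribosomal protein genes (22 measured, median 0.26, adjusted p = 0.00548) and oxidative phosphorylation genes (23 measured, median 0.29, adjusted p = 0.0146) had no called member over all genes or adjusted over the list alone. Both had adjusted p = 0.625 with an estimated correlation, and the oxidative phosphorylation list was not called without CD103- Sirpa+ replicate 2 (mean difference 0.12 against 0.29, adjusted p = 0.406) or with array weights (adjusted p = 0.0749). Neither the ribosomal nor the oxidative phosphorylation list was called when genes below the median signal were left out (adjusted p = 0.0697 and 0.152). Monocyte markers just missed the threshold as a list (camera adjusted p = 0.0519). Of 19 genes 6 were lower in CD103+ Sirpa+ DC and 13 did not pass (4 higher and 7 lower adjusted over the list alone). The cDC2 list (2 higher and 1 lower of 20) and the MHC class I list (1 higher of 17) missed it too (camera adjusted p = 0.0539 and 0.0519). For 6 of the 12 called lists the list means of the arrays overlapped between the groups: MHC class II, Toll-like and NOD-like receptors, interferon response, immediate early, ribosomal and oxidative phosphorylation genes. Of the splits of these arrays, 21 of 56 gave as many called lists as the real one, and splits other than the real one called a median of 9.

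In total 872 genes differed between the Sirpa+ subsets, 548 higher (62.8%) and 324 lower in CD103+ Sirpa+ DC, and 12 of 36 lists passed (19 with the values as deposited). With the values as deposited 960 genes were called, 491 of them among the 872, with 87.2% higher in CD103+ Sirpa+ DC and a median difference over all genes of 0.22; with array medians subtracted 2144 were called, 84.7% of them higher. The count rested on single arrays: it was 115 without CD103- Sirpa+ replicate 2, 2292 without CD103- Sirpa+ replicate 1, 1378 without CD103+ Sirpa- replicate 1, and 374, 366, 308 and 321 without CD103+ Sirpa+ replicates 2, 3, 4 and 5. Of the 79 called genes chosen for naming in this comparison, 28 kept their call without CD103- Sirpa+ replicate 2, among them ITGAE, DSG2, IL22RA2, CDH17, ELOVL6, CMA1, IL1RL1, RAB27B and MKI67, whereas CPA3, CTSG, MAOB, TPSD1, S100A8, TIMP3, GATA2, RGS13, BTLA, DNASE1L3, IFI44L, MX1, HLA-DOA, HLA-DMA, LY96 and FOSB did not. Of these CPA3, S100A8, MX1, HLA-DOA, HLA-DMA and FOSB also lost their call without at least 1 other array. With the mean of the mast cell markers as a covariate limma called 0 genes in this comparison, with 914 at an unadjusted p under 0.05, and with the interquartile range of each array as a covariate it called 2. Of the called lists other than the mast cell markers themselves, 10 of 11 were not called with the mast cell covariate, all but B and plasma cell markers (adjusted p from 0.372 to 0.961). With the interquartile range 8 of 12 were not called, all but the mast cell, B and plasma cell, immediate early and ribosomal lists (adjusted p from 0.0826 to 0.854).

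The CD103+ Sirpa- and CD103- Sirpa+ subsets differed in both gate markers. XCR1 was 73.0-fold and CLEC9A 49.5-fold higher in CD103+ Sirpa- DC. ENPP1 was higher by a log2 difference of 7.14 ± 0.47 (SE, n = 3 and 3, adjusted p = 5.09e-06), or 141-fold. The means of ENPP1 and AIM2 in CD103- Sirpa+ DC (3.72 and 3.93) and of HPGDS in CD103+ Sirpa- DC (4.00) lay below the lower quartile of all probe sets (4.02), where signal over background was not tested, so the size of their folds is uncertain. DPP4, a cell surface dipeptidase, was 22.3-fold higher and VCAM1, a vascular cell adhesion molecule, 21.5-fold higher. GCSAM, C1orf54, GPR31, AIM2 and TSPAN6 ranged from 21.9-fold to 19.0-fold. In CD103- Sirpa+ DC CPA3 was 99.5-fold higher, with a log2 difference of -6.64 ± 1.22 (SE, adjusted p = 0.00649), and HPGDS 73.5-fold higher. CLC, the Charcot-Leyden crystal protein gene of eosinophils and basophils, was 58.4-fold higher and ALOX5AP, which encodes the activating protein of 5-lipoxygenase, 27.5-fold higher. IL1RL1, HPGD, CMA1, CTSG, GCSAML and RAB27B ranged from 40.4-fold to 21.5-fold. All 20 of these genes kept their call with the values as deposited, with array medians subtracted and without any single array. With the mast cell marker mean as a covariate 6 genes were called in the whole comparison. Without CD103+ Sirpa+ replicate 5 and CD103- Sirpa+ replicate 2 together, 445 of the 1050 called genes kept their call, which is not given gene by gene here.

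Of the cDC1 markers 21 of 22 were higher in CD103+ Sirpa- DC and 1 did not pass (22 adjusted over the list alone; median 3.02, camera adjusted p = 2.44e-37 and adjusted p = 0.00899 with an estimated correlation). Fc and complement receptors were lower for 10 of 16, with 6 not past (12 lower and 1 higher adjusted over the list alone, adjusted p = 3.57e-12 and adjusted p = 0.0119 with an estimated correlation). Examples were FCGR2A (11.6-fold), C3AR1 (11.8-fold) and FCER1G (7.71-fold). Of 20 cDC2 markers 9 were lower, 1 was higher and 10 did not pass (12 and 1 adjusted over the list alone, adjusted p = 3.78e-10 and adjusted p = 0.114 with an estimated correlation), with ZEB2, a transcriptional repressor, 16.7-fold lower and ITGAM, the CD11b gene, 10.5-fold lower. Cell cycle genes were higher for 9 of 25, with 16 not past (19 adjusted over the list alone; median 1.11, adjusted p = 6.87e-14 and adjusted p = 0.197 with an estimated correlation). MKI67 was 4.41-fold higher and PLK1, a mitotic kinase, 3.43-fold higher. MHC class I presentation genes were higher for 4 and lower for 1 of 17, with 12 not past (6 and 1 adjusted over the list alone, adjusted p = 0.00139 and adjusted p = 0.206 with an estimated correlation). The peptide transporter gene TAP2 was 3.12-fold higher, and CYBB, the oxidase subunit gene on that list, was 16.1-fold lower. MHC class II presentation genes were higher for 2 of 18, with 16 not past (4 adjusted over the list alone, adjusted p = 8.10e-04 and adjusted p = 0.411 with an estimated correlation). An example was HLA-DOB (5.78-fold). CD103- Sirpa+ replicate 2 had an MHC class II mean of 8.46, whereas replicates 1 and 3 (9.67 and 9.71) lay within the CD103+ Sirpa- range (9.60 to 10.13). Without replicate 2 the list was not called (mean difference 0.18 against 0.59, adjusted p = 0.0854).

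Mast cell and basophil markers were lower in CD103+ Sirpa- DC for 10 of 11 genes and 1 did not pass (11 adjusted over the list alone; median -4.24, adjusted p = 4.08e-16 and adjusted p = 0.114 with an estimated correlation). Examples were KIT, the stem cell factor receptor (17.4-fold), and SLC18A2, the vesicular monoamine transporter (21.0-fold). Monocyte markers were lower for 6 and higher for 1 of 19, with 12 not past (11 and 1 adjusted over the list alone, adjusted p = 8.35e-07 and adjusted p = 0.114 with an estimated correlation). An example was SERPINA1 (6.04-fold). Macrophage markers were lower for 5 of 24, with 19 not past (8 adjusted over the list alone, adjusted p = 6.97e-08 and adjusted p = 0.206 with an estimated correlation). An example was CSF1R (8.98-fold). Neutrophil and eosinophil markers were lower for 4 of 12, with 8 not past (4 adjusted over the list alone, adjusted p = 7.54e-05 and adjusted p = 0.227 with an estimated correlation). Examples were CLC and MMP9 (12.8-fold). B and plasma cell markers were lower for 2 of 17, with 15 not past (5 adjusted over the list alone, adjusted p = 2.57e-05 and adjusted p = 0.227 with an estimated correlation). Plasmacytoid DC markers were lower for 2 of 17, with 15 not past (4 adjusted over the list alone, adjusted p = 0.0461 and adjusted p = 0.382 with an estimated correlation), and this list was not called with the values as deposited, with array medians subtracted (adjusted p = 0.0554 and 0.0670), without CD103+ Sirpa- replicate 2 or 3 (adjusted p = 0.133 and 0.108) or without CD103- Sirpa+ replicate 3 (adjusted p = 0.226).

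Cytokine genes were lower for 3 of 24, with 21 not past (3 adjusted over the list alone, adjusted p = 0.00862 and adjusted p = 0.114 with an estimated correlation). An example was CSF1, the macrophage colony-stimulating factor (11.9-fold). Growth factor receptors of myeloid cells were lower for 5 of 22 and higher for 1, FLT3 (6.21-fold), with 16 not past (7 and 1 adjusted over the list alone, adjusted p = 0.0280 and adjusted p = 0.527 with an estimated correlation). Genes of TGF-beta activation and signalling were lower for 4 and higher for 1 of 25, with 20 not past (6 and 1 adjusted over the list alone, adjusted p = 0.00438 and adjusted p = 0.197 with an estimated correlation). Type I interferon response genes were lower for 3 of 25, with 22 not past (5 lower and 1 higher adjusted over the list alone, adjusted p = 0.00594 and adjusted p = 0.411 with an estimated correlation). An example was SAMD9L (9.36-fold). Phagosome oxidase and antimicrobial genes were lower for 2 and higher for 1 of 16, with 13 not past (5 and 1 adjusted over the list alone, adjusted p = 0.00966 and adjusted p = 0.246 with an estimated correlation). The ribosomal (median 0.29, adjusted p = 0.00438 and adjusted p = 0.468 with an estimated correlation) and oxidative phosphorylation lists (median 0.38, adjusted p = 2.94e-04 and adjusted p = 0.378 with an estimated correlation) were higher and the immediate early list (median -0.31, adjusted p = 0.0239 and adjusted p = 0.598 with an estimated correlation) lower, each with no single member called by limma; adjusted over the list alone 1 immediate early gene was higher and 3 were lower. The immediate early list was not called with the values as deposited, nor was it or the growth factor receptor list with array medians subtracted. Without CD103+ Sirpa- replicate 2 and without CD103- Sirpa+ replicate 1 neither of these lists was called (adjusted p = 0.251 and 0.253 for the immediate early list, 0.104 and 0.310 for the receptors). The immediate early list was not called without CD103+ Sirpa- replicate 1 (adjusted p = 0.113), and its mean difference of -0.27 was -0.42 without CD103+ Sirpa- replicate 3 and -0.17 without CD103- Sirpa+ replicate 1. Without CD103- Sirpa+ replicate 3 the receptor, cytokine and interferon response lists were not called (adjusted p = 0.2005, 0.0678 and 0.0906). The mean difference of the receptors was -0.52, and -0.34 without CD103+ Sirpa- replicate 3, and that of the oxidative phosphorylation genes was 0.40, and 0.22 without CD103- Sirpa+ replicate 2.

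In total 1050 genes differed between these groups, 583 higher (55.5%) and 467 lower in CD103+ Sirpa- DC, and 20 of 36 lists passed (18 with the values as deposited). Of 10 splits 2 gave as many lists, and splits other than the real one called a median of 11. The list means of the arrays overlapped between the groups for 5 of the 20, the MHC class II, growth factor receptor, immediate early, ribosomal and oxidative phosphorylation lists. With the mast cell covariate 12 of the 19 called lists other than the mast cell markers were not called (adjusted p from 0.0739 to 0.999), and those that were called were the cDC1, cDC2, monocyte, macrophage, Fc and complement receptor, cytokine and interferon lists. With the interquartile range as a covariate the MHC class II and plasmacytoid lists were not called (adjusted p = 0.0516 and 0.214). With the values as deposited 530 genes were called, 455 of them among the 1050, with 44.3% higher in CD103+ Sirpa- DC. The count was 525 and 522 without CD103+ Sirpa- replicates 2 and 3, and 621 without CD103- Sirpa+ replicate 2. It was 399 with only these 2 groups in the fit, 394 of them among the 1050.

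Genes higher in 1 subset than in both others were counted from the same fit. CD103+ Sirpa- DC had 176, led by XCR1, CLEC9A, ENPP1, TSPAN6 and GPR31, whose smaller difference ran from 57.8-fold to 15.7-fold; CADM1, a cell adhesion molecule, followed at 10.7-fold. CD103+ Sirpa+ DC had 106, led by DSG2 (12.3-fold), IL22RA2 (7.03-fold), ITGB1BP2 (6.19-fold) and DNAJC5B (5.52-fold), with LAMP5 at 5.195-fold and the efflux transporter gene ABCB1 at 4.39-fold. CD103- Sirpa+ DC had 155, led by CPA3 (34.8-fold), CMA1 (26.6-fold), IL1RL1 (23.2-fold) and HPGD (20.1-fold), all with the mast cell marker mean at 9.65 in that group. Independent lists would have shared 8.11, 13.8 and 8.23 genes, and 20 simulated data sets without group differences gave 0 at most. At most 2 genes were called in a contrast of those data, so the 0 was nearly fixed beforehand and does not bound the overlap of contrasts that share a group. When the 5 CD103+ Sirpa+ arrays were divided between the contrasts, a median of 5 genes (range 0 to 34 over 20 divisions) was shared against 0.177 for independent lists. Groups of 3 arrays could not be divided with 2 arrays in each part, so part of the 176 and 155 may come from the shared arrays. With the values as deposited the counts were 77, 188 and 110, and the counts rested on single arrays. For CD103+ Sirpa- DC the count was 95 and 103 without CD103+ Sirpa- replicates 2 and 3. For CD103+ Sirpa+ DC it was 60 without CD103+ Sirpa- replicate 2, 68, 63, 53 and 62 without CD103+ Sirpa+ replicates 2, 3, 4 and 5, and 28 without CD103- Sirpa+ replicate 2. For CD103- Sirpa+ DC it was 89 without CD103+ Sirpa- replicate 2 or 3, 91, 93, 86 and 83 without CD103+ Sirpa+ replicates 2, 3, 4 and 5, 37 without CD103- Sirpa+ replicate 2 and 334 without CD103- Sirpa+ replicate 3.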

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

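The tests of a single array and of expression by the DC themselves were chosen after the results were seen, and the list of further mast cell genes was written before its values were. Among 90 results tested within the 5 CD103+ Sirpa+ arrays, 10 had 1 array whose gap to the nearest other array exceeded 0.71 of the group's range, and chance gives this for about 1 in 20 results.

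In CD103+ Sirpa+ replicate 1, 6 genes stood above the other 4 arrays: HPGD (ratio of gap to range 0.888), MAOB (0.87), GCSAML (0.805), TIMP3 (0.76), TPSD1 (0.759) and CTSG (0.755). The log2 signal of TPSD1, a tryptase gene, was 9.02 there and that of CTSG 7.82. This array also had the highest mean of the mast cell and basophil markers among the CD103+ arrays, 7.82.

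For the higher signal of mast cell genes in the CD103- Sirpa+ arrays, a hypothesis is that mast cells or their RNA were present in these sorts; the labels name no marker of the sort beyond CD103 and Sirpa. Mean log2 signals in CD103- Sirpa+ and CD103+ Sirpa+ DC were 12.46 and 7.33 for CPA3, 11.21 and 9.51 for KIT, 10.33 and 6.04 for CTSG, and 10.20 and 7.19 for HPGDS; KIT is also on the list of growth factor receptors, and HPGDS also differed between the CD103+ subsets. Of 6 further mast cell genes 4 were measured, fewer than the 5 a list test needed, and their median difference was -1.71 in the direction of CD103- Sirpa+ DC, past the bound set for this explanation, although MRGPRX2 differed by only -0.05. A single array as the source is argued against, since the list means of CD103- Sirpa+ replicates 1 and 2 lay 2.80 and 2.55 above the highest other array; that of replicate 3 lay 0.14 above it. Expression by the DC themselves stays open. Groups accounted for 80.5% of the variance of the marker mean, and bulk RNA of a sorted gate does not tell mast cells from DC expression. The marker mean also varied within gates, at 10.62, 10.38 and 7.96 in the CD103- Sirpa+ arrays and from 5.90 to 7.82 in the CD103+ Sirpa+ arrays.

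The other flagged values carry no tested explanation. SIRPA was lower in CD103+ Sirpa+ replicate 2 (log2 signal 7.77, ratio 0.819). FAM171B was higher in replicate 2 (ratio 0.765) and SYT2 lower in replicate 5 (ratio 0.765). The deposited median of CD103+ Sirpa+ replicate 5 was 6.85 (ratio 0.944).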

How the results depend on the processing

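The mast cell and interquartile range covariates and the omission of a pair of arrays were chosen after the data were seen. The quantile normalization listed beforehand as an alternative became the setting of the report, and no value is given for the mast cell list, or for members of it, with the mean of its own members as a covariate. Counts are given for CD103+ Sirpa- against CD103+ Sirpa+ (first), CD103+ Sirpa+ against CD103- Sirpa+ (second) and CD103+ Sirpa- against CD103- Sirpa+ (last), and for genes higher in 1 subset in the order CD103+ Sirpa-, CD103+ Sirpa+, CD103- Sirpa+. The cause of a change was not tested unless fewer arrays or genes entered by construction. No direction turned for a called named gene or list under any alternative except the mast cell covariate. Of the called named genes 77 of 90, 56 of 79 and 80 of 103 kept their call with the values as deposited, and 83, 70 and 92 with array medians subtracted. The mean of a gene's probe sets and the trended prior left every count within 1.5 times. Signal over background was not tested, since no background value was used here, and a log2 change of 0.5 was mostly missed in simulated data.

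With the values as deposited the last comparison had 530 genes, the subsets CD103+ Sirpa- and CD103+ Sirpa+ had 77 and 188 genes, and the second comparison had 19 lists. With array medians subtracted the second comparison had 2144 genes and CD103+ Sirpa+ DC had 242. Without genes below the median signal the first comparison had 10 lists: the monocyte, Toll-like and NOD-like receptor, lectin, maturation, glycolysis and lipid handling lists were not called, nor were the interferon, ribosomal and oxidative phosphorylation lists in the second. With CD103+ Sirpa+ arrays 1 to 3 only, the lectin, Toll-like and NOD-like receptor, cytokine, glycolysis and lysosomal lists of the first comparison and the neutrophil and eosinophil list of the second were not called (adjusted p from 0.0504 to 0.0993, and 0.101). With only the 2 groups compared in the fit, the last comparison had 399 genes and CD103- Sirpa+ DC had 70. Array weights gave 1599 genes in the first comparison, 329 for CD103+ Sirpa- DC and 102 for CD103- Sirpa+ DC. With CD103+ Sirpa+ arrays 1 to 3 only, which are fewer arrays, the comparisons had 343, 58 and 670 genes and the subsets 95, 17 and 18. A minimum log2 difference of 1 left 541 genes in the second comparison and 64 for CD103+ Sirpa+ DC. Camera with an estimated correlation called 2, 0 and 2 lists, and fry 5, 2 and 13; fry's mixed test called 28, 33 and 34.

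The replicate numbers were not stated to mark donors. Arrays were to be paired only if every same-number pair correlated above 0.1. Only 2 of 9 such pairs did (r from -0.26 to 0.42), so the main fit used no pairing. Different-number pairs had r from -0.46 to 0.48. Of 9 arrays 1 correlated best with its own number in both other groups, and 3 had their single best partner at their own number. Deviations from the means of such small groups are tied to each other, so these values cannot show that the arrays are unpaired. Whether groups share donors stays open. With the number as a replicate block the first and second comparisons had 382 and 112 genes and the subsets 102, 19 and 54. With it the Toll-like and NOD-like receptor, cytokine and lysosomal lists of the first comparison (each adjusted p = 0.0765) and the neutrophil and eosinophil list of the second (adjusted p = 0.0745) were not called.

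Leaving out 1 array at a time gave 416 to 819 genes in the first comparison, 115 to 2292 in the second and 522 to 1456 in the last. The subsets had 95 to 251, 28 to 139 and 37 to 334 genes, and the comparisons 10 to 22, 10 to 15 and 16 to 25 lists. The extremes of the second comparison came without CD103- Sirpa+ replicates 2 and 1. Without CD103- Sirpa+ replicate 2 and CD103+ Sirpa+ replicate 5 together, the second and last comparisons had 43 and 481 genes and the subsets CD103+ Sirpa+ and CD103- Sirpa+ had 15 and 12.

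With the interquartile range as a covariate the second and last comparisons had 2 and 651 genes, CD103+ Sirpa+ and CD103- Sirpa+ DC had 1 and 0, and the second comparison had 5 lists. With the mast cell covariate the second and last comparisons had 0 and 6 genes by limma (914 and 1044 at an unadjusted p under 0.05), the subsets had 5, 0 and 0, and the comparisons had 10, 3 and 10 lists. The median size of the differences called in the second comparison then went from 1.11 to 0.62 while the median standard error went from 0.24 to 0.41, so calls ended through both; groups accounted for 80.5% of the variance of this covariate.

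Under the mast cell covariate log2 differences turned sign in the second comparison for FLT3 (-0.050) and KMO (-0.053) and for the mean differences of the Toll-like and NOD-like receptor (-0.14), cell cycle (-0.11), ribosomal (-0.018) and oxidative phosphorylation (-0.13) lists. In the last comparison they turned for HPGD (0.010), GCSAML (0.75), SIGLEC8 (0.37), KRT19 (0.26), HLA-DMA (-0.027), CTSD (0.17), TNFRSF9 (0.82), RDH10 (-0.17) and MAML2 (0.0095), and for the mean differences of the MHC class II (-0.088), TGF-beta (0.091), ribosomal (-0.10) and oxidative phosphorylation (-0.19) lists. The mean difference of the cell cycle list stayed above 0 there (0.044) and only the direction given by camera turned. None of these passed the threshold under this covariate.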

Other observations

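The tests of the scale of replicate 5, of fewer arrays and of epithelial cells were chosen after the results were seen. For the test of array spread the covariate was added after the data were seen, and only its bounds were written before its result. The splits of the samples were set beforehand. IDO1, which encodes the tryptophan-degrading indoleamine dioxygenase and is also on the cDC1 list, was 4.85-fold higher in CD103+ Sirpa- than in CD103+ Sirpa+ DC (log2 difference 2.28 ± 0.35, SE, adjusted p = 0.00152) and 10.6-fold higher than in CD103- Sirpa+ DC. IDO2 was 4.72-fold higher in CD103+ Sirpa+ than in CD103- Sirpa+ DC (adjusted p = 0.00186). The inhibitory receptor gene LILRB2 was 4.05-fold lower in CD103+ Sirpa- than in CD103+ Sirpa+ DC. As a list, tryptophan, prostaglandin and tolerance genes did not pass in any comparison (adjusted p = 0.0598, 0.727 and 0.134). SMAD3, a mediator of TGF-beta signals, had means of 7.89 in CD103+ Sirpa-, 5.69 in CD103+ Sirpa+ and 8.68 in CD103- Sirpa+ DC, and was 4.59-fold higher and 7.98-fold lower in the first and second of these contrasts. The chemokine receptor gene CCR6 was 4.54-fold higher in CD103+ Sirpa+ than in CD103- Sirpa+ DC and the tetraspanin gene CD9 8.78-fold lower. Of all 872 genes called between these Sirpa+ subsets, 111 stayed called without CD103- Sirpa+ replicate 2 and 2 with the interquartile range covariate. With the mast cell covariate 0 did, so the calls of IDO2, SMAD3, CCR6 and CD9 between these subsets ended there.

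Among transcription factors of the DC lineage, 4 were higher and 4 lower of 23 in CD103+ Sirpa- against CD103+ Sirpa+ DC, and 15 did not pass (list adjusted p = 0.0598). PRDM1, a transcriptional repressor, was 7.34-fold lower and ZEB2 9.16-fold lower. Against CD103- Sirpa+ DC 5 were higher and 3 lower (list adjusted p = 0.311), with BCL6 4.33-fold higher. Retinoic acid genes did not pass as a list (adjusted p = 0.641, 0.388 and 0.555). T and NK cell markers (adjusted p = 0.300, 0.442 and 0.999), epithelial markers (0.956, 0.603 and 0.355), stromal markers (0.641, 0.295 and 0.321), chemokine receptors (0.219, 0.603 and 0.336), integrins (0.276, 0.603 and 0.321) and Notch genes (0.296, 0.388 and 0.0661) did not pass either. Median and mean differed in sign for several lists, none of them called. In the first comparison these were the plasmacytoid (0.03 and -0.46), epithelial (0.12 and -0.10), MHC class II (-0.02 and 0.07) and phagosome oxidase and antimicrobial (0.0067 and -0.48) lists, and the ribosomal list had a median of 0.02 and a mean of 0.01 while camera gave it as lower. In the second they were the plasmacytoid (-0.18 and 0.13), epithelial (-0.16 and 0.04) and cytokine (-0.04 and 0.0066) lists. In the last they were the T and NK cell (-0.0059 and 0.07), Toll-like and NOD-like receptor (-0.03 and 0.22), retinoic acid (0.0018 and -0.08) and glycolysis (0.10 and -0.21) lists.

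The number of genes called between CD103+ Sirpa+ and CD103- Sirpa+ DC depended on single arrays. The lowest count without another CD103+ Sirpa+ array was 0.96 of the count without replicate 5. Quantile normalization had already removed the other scale of replicate 5, so these counts cannot test that scale as the source. They show only that leaving out replicates 2, 3, 4 or 5 gave similar counts (374, 366, 308 and 321). A loss of power from 1 array fewer is argued against as the whole cause, since the counts without each CD103- Sirpa+ array differed 19.9-fold. A candidate explanation that stays open is array quality, seen as a narrower spread of the deposited values: with the interquartile range of each array as a covariate the median size of the called differences was 0.715 of that without, between the bounds set for and against it, from 1.11 to 0.79 with the median standard error going from 0.24 to 0.31. Groups accounted for 53.8% of the variance of that range, and a biological difference between the sorts was not tested.

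CDH17 and DSG2, adhesion genes of epithelia, were higher in CD103+ Sirpa+ than in CD103- Sirpa+ DC, with means of 11.81 against 9.06 and 8.86 against 4.54. Epithelial cells in the sort are argued against, because the median difference of the epithelial list was -0.16: KRT8 lay at 7.08 against 6.91, VIL1 at 4.87 against 4.86 and APOA4 at 5.73 against 6.17. EPCAM was 2.49-fold higher and KRT19 2.13-fold lower, and KRT19 was not called with the values as deposited or without CD103- Sirpa+ replicate 2 (adjusted p = 0.0941). Expression by the DC themselves may remain as a hypothesis that these arrays cannot test. The DSG2 call ended when the pair of arrays in doubt was left out, and the calls of both ended with the mast cell and interquartile range covariates.

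Other splits of the samples were used to ask whether as many genes are called when arrays change groups. In the first comparison 1 of 56 splits, the real one, gave 718 genes, and the highest other gave 3. In the second 1 of 56 splits gave 872, and the highest other gave 1. Splits that mix differing groups widen the spread within groups, so few calls in them are likely by construction. The labels do not state separate donors, so these splits do not exclude chance between donors or sorts. In the third 10 splits are too few for a share under 0.05 (1 split with as many; real value 1050, highest other 0). For genes higher in 1 subset, 100 splits were used, the real one among them. Only the real one gave 176 for CD103+ Sirpa- DC (highest other 105) and 106 for CD103+ Sirpa+ DC (highest other 0). For CD103- Sirpa+ DC 2 gave 155 or more, the real one included (highest other 216). Each share was under 0.05. The split with 105 kept all 3 CD103+ Sirpa- arrays together, so 105 is not a level reached without that group. The split with 216 put CD103+ Sirpa- replicate 1 with CD103- Sirpa+ replicates 2 and 3, which are the arrays with the narrowest interquartile ranges (2.77, 2.65 and 2.76, others from 2.96 to 3.21) and points to a structure of the samples. For called lists chance was not excluded in the first comparison (6 of 56 splits gave 16 or more, highest other 21) or the second (21 of 56 gave 12 or more, highest other 22), and in the third 10 splits are too few (2 gave 20 or more, highest other 24). Splits other than the real ones called a median of 8, 9 and 11 lists in the 3 comparisons. Camera at the preset correlation thus called many lists also when arrays were exchanged between groups. Such splits can keep part of the real contrast, so these medians are not counts for groups that do not differ.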
